A study of Homo sapiens with 12 samples.

How the data were processed

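The labels describe 12 libraries from Huh7 cells, with 3 replicates each of shNC input, shNC MeRIP, shNSUN2 input and shNSUN2 MeRIP. All 12 were assigned to groups from their titles before the data were examined. The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4 and the genome build hg19 for these libraries.

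Per the file headers, the gene table holds raw counts and counts normalized with edgeR by the authors, and the lncRNA table holds raw and normalized counts per transcript. The 30 peak lists give, for each peak, a score, a p-value on a logarithmic scale, a fold enrichment and a false discovery rate, per the file headers, and the peak names carry the name of the caller MACS. The peak caller's version and settings are not given in the sources used here. All of these values stand under sample names made of the letter C or P and a number. A name was accepted for a library only if it appeared as a word in that library's title, description, source name or characteristics, and no name did. In the expression tables, only columns headed with such a name and the word input were counted. In total 160 columns of per-sample values matched no sample, 40 of them in the 2 expression tables and 120 in the 30 peak lists. The expression columns carry 10 names headed as input, more than the 3 shNC and 3 shNSUN2 input libraries. If each name is a different sample, some of these columns belong to samples outside the 12 libraries. Which ones is not known, and none of the 160 columns was used in any step.

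The columns used were the transcript start, end and length of the lncRNA table, which are annotation in bases as deposited by the authors, and other than these no column of numbers was read. In 8113 transcripts the length equalled the end minus the start, and in 0 it equalled the end minus the start plus 1. Starts were therefore taken to count from 0 and were converted to count from 1. Repeated lines of a transcript were used once, at its first line. Gene names were matched to symbols in the RefSeq annotation of GRCh38.p14, keeping symbols with 1 gene on a chromosome. A transcript counted as inside a gene when it extended no more than 1000 bases beyond the gene's span. Shares are given with exact Clopper-Pearson intervals at the 95% level, which cover counting error only, and transcripts of 1 gene are not independent. The matching step was tested on simulated coordinates with known answers. The simulated transcripts lay wholly inside or wholly outside their gene, so the 1000-base margin and the conversion of starts were not exercised. Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1 were used.

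The planned analyses were not run: differential expression between input libraries, tests of fixed gene lists, MeRIP enrichment as an interaction between library kind and knockdown, peak numbers, gained and lost peaks, and the overlap of changed peaks with changed genes. The rule for named genes asked for NSUN2, the largest changes in each direction and members of the fixed gene lists. No gene is reported under this rule, because no measured value could be assigned to a library. A comparison of the C with the P columns was not made, since no label says what those columns are.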

Results

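The labels of the series describe an experiment on Huh7, an established human hepatocellular carcinoma cell line. Cells carried either an empty plasmid (shNC) or a plasmid expressing a short hairpin RNA against NSUN2 (shNSUN2). NSUN2 is a methyltransferase that forms 5-methylcytosine (m5C) in tRNAs, other non-coding RNAs and some mRNAs. Total RNA was fragmented, and fragments bound by an antibody against m5C were recovered and sequenced (MeRIP), beside a library from RNA that did not pass through the antibody step (input). The 12 libraries fall into 4 groups of 3 replicates, namely shNC input, shNC MeRIP, shNSUN2 input and shNSUN2 MeRIP.

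The design implied a comparison of transcript levels between the shNSUN2 and shNC input libraries. It also implied a comparison of m5C peaks between the shNSUN2 and shNC cells. A further comparison, of m5C enrichment (MeRIP over input) between shNSUN2 and shNC cells, would use all 12 libraries. None of these comparisons could be made, because no measured value could be assigned to a library of the series. The files analysed here were 2 expression tables, one for genes and one for long non-coding RNA (lncRNA) transcripts, and 30 peak lists covering 3 RNA classes (mRNA, lncRNA and circular RNA). Their columns and sheets carry 10 sample names, 5 beginning with C and 5 beginning with P, each with a number. Of these names, 0 match a label of any of the 12 libraries. The C and P sets also differ in size from the groups of 3 replicates in the labels. In the expression tables, the columns counted as per-sample values were those headed with these names and the word input. The 10 names in these headings outnumber the input libraries in the labels, 3 for shNC and 3 for shNSUN2. If each name is a different sample, some of them belong to samples outside the 12 libraries. No level of NSUN2, no count of changed genes and no number of m5C peaks is therefore reported for shNC or shNSUN2 cells, and the depth of the 12 libraries is unknown.

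The annotation columns of the lncRNA table belong to no sample and could be examined. They describe 53736 transcripts under 27011 gene names. For 40366 transcripts the gene name had exactly 1 gene on the same chromosome in the RefSeq annotation of GRCh38. Of these, 38142 lay inside that gene's GRCh38 span, with 1000 bases allowed on either side. This is 94.5% of the transcripts with a match (95% exact Clopper-Pearson interval 94.3% to 94.7%). As a background, the gene spans were shuffled at random among the matched transcripts of each chromosome. With the same 1000 bases allowed, 97 of the 40366 transcripts lay inside the drawn gene. That background share was 0.24% (95% interval 0.19% to 0.29%). The submitters' processing notes for the 12 libraries name the build hg19. An hg19 annotation was not used here, so the corresponding share for hg19 was not measured and the 2 builds were not compared. The shuffled background cannot tell the builds apart, because it uses GRCh38 spans only.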

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

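No paired analysis was possible because no column of the tables could be assigned to a replicate of the series. The alternatives planned for expression, gene lists, MeRIP enrichment and peaks were not run for the same reason. The share of lncRNA transcripts inside GRCh38 genes and its alternatives were chosen after seeing the data. With no bases allowed outside the gene's span, 85.5% of the matched lncRNA transcripts lay inside the GRCh38 gene of the same name, against 94.5% with 1000 bases allowed. When an overlap of at least 1 base was enough, the share was 98.8%.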
